A study of Caenorhabditis elegans with 4 samples.

How the data were processed

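Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on wild-type N2 Caenorhabditis elegans at the L3 larval stage, grown at 20 °C, with an affinity-purified rabbit polyclonal antibody against NURF-1. Per the labels' protocols, frozen and ground worms were crosslinked for 20 minutes with EGS, an amine-reactive linker that joins neighbouring proteins, and for 10 more minutes with EGS plus formaldehyde, then sonicated. The labels describe 4 libraries, of which 2 are NURF-1 ChIP replicates and 2 are input DNA (chromatin that was not immunoprecipitated). The labels do not say whether the 2 ChIP replicates came from separate cultures, so the spread between them may be technical in part.

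The values used here are 3 peak lists made by the authors, 1 for each ChIP replicate and 1 for the whole series, called the combined list below. Peaks were called with MACS on the WormBase WS220 genome build, per the file headers. Reads were aligned with BWA to ce10, the other name of that build, per the submitters' processing notes; versions, read filters, the use of the input in peak calling and the way the combined list was made are not given in the sources used here. Each peak carries its first and last base (1-based) and a score, which the authors deposited without stating its scale. The lowest score was 1.31 in replicate 2, 1.32 in the combined list and 1.35 in replicate 1, each just above the 1.30 that is the −log10 of 0.05, but the scale is not known and the score was used only to rank and describe peaks within a list, and to correlate ranks and scores between the replicates. The lists give no reads, so sequencing depth is unknown and no value for the input libraries was analysed here. Every interval below covers counting error over peaks only.

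Peaks were compared by overlap of at least 1 bp over the 6 nuclear chromosomes. The last peak end found on a chromosome in any list was taken as the chromosome's length. Chance overlap was measured by shifting all peaks of replicate 2 around each chromosome by a random distance of at least 100 kb, 1000 times, which keeps widths and spacing; the one-sided permutation p cannot go below 0.001. Score differences and centre-to-arm ratios were tested with chromosomes as units, by an exact two-sided sign-flip permutation test over 6 chromosomes whose smallest p is 0.031. X was compared with the 5 autosomes by an exact permutation over the 6 chromosomes, whose smallest one-sided p is 0.167. The chromosomes of a list come from the same data. Tests and SDs over chromosomes therefore measure how alike chromosomes are within a list, not variation between libraries or cultures. The 8 main tests formed 1 family for Benjamini-Hochberg adjustment. Shares carry 95% Wilson intervals and densities 95% exact Poisson intervals. On simulated lists, all planted shared peaks were recovered, which was certain because they were moved by less than a peak's width. Of 200 pairs of independent simulated lists, 8 gave permutation p under 0.05. Those lists were shorter, had peaks placed evenly at random and were tested with fewer shifts. They therefore do not show how the test behaves with the uneven placement of the real peaks.

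Alternatives fixed before the data were examined were a 50% reciprocal overlap, midpoints within 200 bp, the top 50% and top 10% of peaks by score, equal numbers of peaks per replicate, each replicate list alone, combined peaks found in both replicates, covered bases in place of peak numbers, and another division of chromosomes into centre and arms. Leaving out peaks within 20 kb of a chromosome end and taking autosomes alone were added later. By the naming rule, also fixed beforehand, the 10 highest-scoring combined peaks found in both replicates are named by position. A further 2 comparisons set beforehand, of peaks with annotated genes and of bound genes across gene lists, were not made: the gene table at hand was of the WBcel235 build, and coordinates of different builds were not mixed. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.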

Results

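NURF-1 is the C. elegans counterpart of mammalian BPTF and the large subunit of the NURF nucleosome-remodelling complex, which contains the ISWI-type ATPase ISW-1. Its genomic binding was mapped by ChIP-seq in wild-type L3 larvae. The design holds 2 NURF-1 ChIP replicates, 2 input libraries and no other condition, so the comparisons it implies are between the replicates, between each replicate and the combined peak list, and between regions of the genome. Replicate 1 held 9065 peaks with a median width of 403 bp, covering 4.99% of the nuclear genome. Replicate 2 held 7519 peaks with a median width of 343 bp, covering 3.38%. The combined list held 10483 peaks with a median width of 387 bp, covering 5.88%. All but 1 peak in replicate 2 and 1 in the combined list lay on nuclear chromosomes. Positions below are on WS220.

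The first comparison asked how far the replicates located NURF-1 at the same sites. Of the replicate 1 peaks, 5779 (63.8%, 95% Wilson interval 62.8 to 64.7) overlapped a replicate 2 peak. Of the nuclear replicate 2 peaks, 6259 (83.3%, 82.4 to 84.1) overlapped a replicate 1 peak. Randomly shifted lists overlapped in 7.77% and 9.61% of peaks on average, and in 8.71% and 10.8% at most. The bases covered by both lists made up 0.518 of the bases covered by either (Jaccard index), against a mean of 0.0233 after shifting. All 3 overlaps exceeded every one of 1000 shifts (permutation p = 0.001, the smallest they can give, adjusted p = 0.002). The 2 shares differ partly because the replicate 1 list is longer. With equal numbers of top peaks taken from each replicate they were 72.4% for replicate 1 and 79.6% for replicate 2.

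Sharing followed peak strength. In replicate 1 the shared peaks had a median score of 41.1 and a median width of 637 bp, against 5.90 and 224 bp for unshared peaks. In replicate 2 the medians were 15.6 and 397 bp for shared peaks and 4.44 and 206 bp for unshared ones. The difference in median score, shared minus unshared, averaged 35.6 ± 4.53 (SD over 6 chromosomes) in replicate 1 and 11.6 ± 2.1 in replicate 2. Shared peaks scored higher on 6 of 6 chromosomes in each replicate (exact sign-flip permutation p = 0.031, the smallest possible, adjusted p = 0.0417). The size of the difference depended on the peaks taken. With the top 50% of each list it was 74.7 and 30.6, and with the top 10% 23.4 and 22.8. These cuts were made in both lists, so a peak whose partner scored below the cut counted as unshared. A positive difference under them is therefore partly built in. With a 50% reciprocal overlap it was 21.5 in replicate 2. All 907 peaks in the highest-scoring 10% of replicate 1 and all 752 in that of replicate 2 had a partner in the other replicate. In the lowest-scoring 10% the shares were 21.4% (18.8 to 24.2) and 51.7% (48.2 to 55.3). Across 5672 one-to-one pairs of shared peaks, scores ranked alike (Spearman rho = 0.86, Pearson r = 0.85, permutation p = 0.001 by rotating the order of peaks along the genome), a relation across peaks, which are not independent replicates. Within the top 10% of both lists rho was 0.38 over 621 pairs. That cut narrows the range of scores in both lists, which by itself lowers a correlation. Replicate 1 gave the wider peak in 83.8% of pairs.

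**Figure D1:**
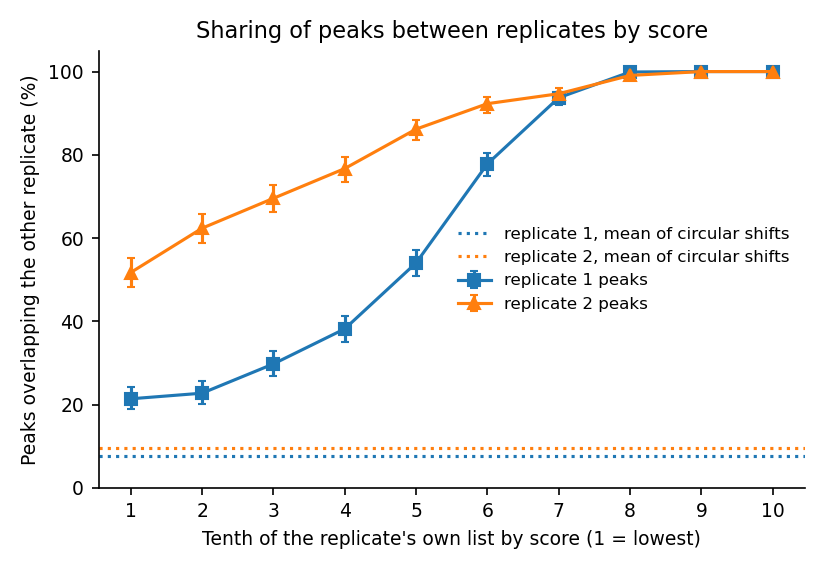
Percent of each replicate's peaks that overlap a peak of the other replicate (y axis), by successive 10% steps of its own list ordered by score (x axis), with 95% Wilson intervals; dotted lines are the means of 1000 circular shifts. Sharing rises from 21.4% to 100% in replicate 1 and from 51.7% to 100% in replicate 2.

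The combined list was then set against the replicates. Of its 10482 nuclear peaks, 5543 (52.9%, 51.9 to 53.8) overlapped a peak in both replicates, 2907 (27.7%) in replicate 1 alone and 688 (6.56%) in replicate 2 alone. A further 1344 (12.8%, 12.2 to 13.5) overlapped no peak of either replicate. Peaks found in both replicates had a median score of 52.7 and a median width of 734 bp. Median scores were 7.50 for peaks found in replicate 1 alone, 5.69 for replicate 2 alone and 4.2 for neither. The combined list contained 97.8% of replicate 1 peaks and 93.1% of replicate 2 peaks. Only 48 combined peaks had exactly the boundaries of a replicate 1 peak and 2 those of a replicate 2 peak.

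The 10 highest-scoring combined peaks found in both replicates had combined scores of 201.03 to 212.12 and widths of 826 to 1931 bp. The highest lay on X at 5952766 to 5953731 (combined score 212.12), followed by V at 12317841 to 12319072 (211.24), II at 7373693 to 7374779 (210.99), I at 3546546 to 3548285 (207.17) and III at 3915377 to 3917307 (205.99). The other 5 were on II at 9745645 to 9746827 (203.85), I at 12004491 to 12005425 (203.36), V at 1150361 to 1152143 (201.94), II at 8324880 to 8325705 (201.58) and II at 649797 to 650962 (201.03). Chromosome II thus held 4 of the 10 and chromosome IV none. Their scores were 201.79 to 235.31 in replicate 1 and 159.67 to 293.85 in replicate 2. Each site lay at or above the 99.16 percentile of replicate 1 scores and the 97.18 percentile of replicate 2 scores. Which genes these sites belong to was not analysed here.

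NURF-1 peaks were least dense on the X chromosome and densest on chromosomes III and I. The combined list held 157 peaks per Mb on III (95% exact Poisson interval 151 to 164), 149.6 on I (143 to 156), 109.8 on IV (104.95 to 114.8), 102.7 on II (97.7 to 108), 76.7 on V (73.0 to 80.5) and 54.5 on X (51.1 to 58.1). The density on X was 0.457 of the autosomal mean of 119.2 ± 33.7 (SD, n = 5 autosomes). It was 0.423 in replicate 1 and 0.480 in replicate 2. X was the lowest of 6 chromosomes in each list (exact permutation p = 0.167, the smallest this design allows, adjusted p = 0.190), so the test could not have passed 0.05. Strong peaks were rarer still on X. Of the X peaks in the combined list, 5.80% (4.49 to 7.45) were among the top 10% by score, against 10.4% (9.84 to 11.07) of autosomal peaks. In replicate 1 the shares were 4.75% and 10.5%, and in replicate 2 they were 3.05% and 10.8%. The X-to-autosome density ratio of these strong peaks was 0.252 in the combined list, 0.189 in replicate 1 and 0.135 in replicate 2. Each was below all ratios from 1000 random draws of as many peaks from the same list (permutation p = 0.001, the smallest possible, a test that treats peaks as independent and was chosen after the data were seen).

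**Figure D2:**
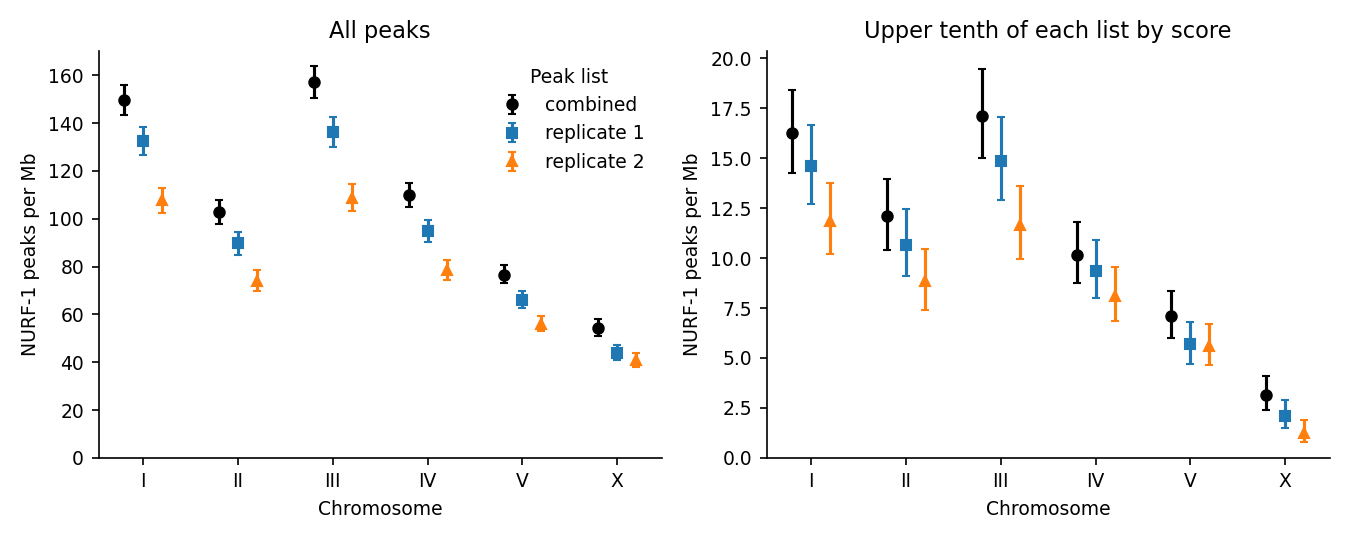
NURF-1 peaks per Mb (y axis, linear) on each nuclear chromosome (x axis) in the combined list and both replicate lists, for all peaks (left) and for the top 10% of each list by score (right); bars are 95% exact Poisson intervals. X lies lowest in every list, at 54.5 peaks per Mb in the combined list against 157 on III.

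Chromosome centres and arms were compared because the autosomes of C. elegans have gene-rich centres and repeat-rich arms. Each chromosome was divided into 3 equal segments, of which the middle is called the centre and the outer 2 the arms. Over all combined peaks, no difference between centres and arms was detected: the mean log2 ratio of centre to arm density was -0.06 ± 0.22 (SD, n = 6 chromosomes), with centres denser on 2 of 6 (exact sign-flip permutation p = 0.562). Chromosome V had 87.6 peaks per Mb in its centre and 71.2 in its arms, while X had 46.9 and 58.3. Among the top 10% of peaks by score, centres were denser on 6 of 6 chromosomes, by 0.59 ± 0.29 on the log2 scale or 1.50-fold (exact permutation p = 0.031, the smallest possible; adjusted p = 0.344 over this result and its alternatives, 11 settings, and 0.117 over all 15 centre-to-arm tests run, which share peaks). Added later for the replicates, this setting gave 0.68 ± 0.26 in replicate 1 and 0.62 ± 0.25 in replicate 2, again with 6 of 6 chromosomes each. The contrast was widest on V, with 10.6 strong peaks per Mb in the centre and 5.38 in the arms, and on II, with 17.1 and 9.62. It was narrowest on X, with 3.56 and 2.96. The top 10% exceeded the remaining peaks in log2 centre-to-arm ratio by 0.72 ± 0.19 (6 of 6 chromosomes, exact permutation p = 0.031), a contrast chosen after the data were seen.

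**Figure D3:**
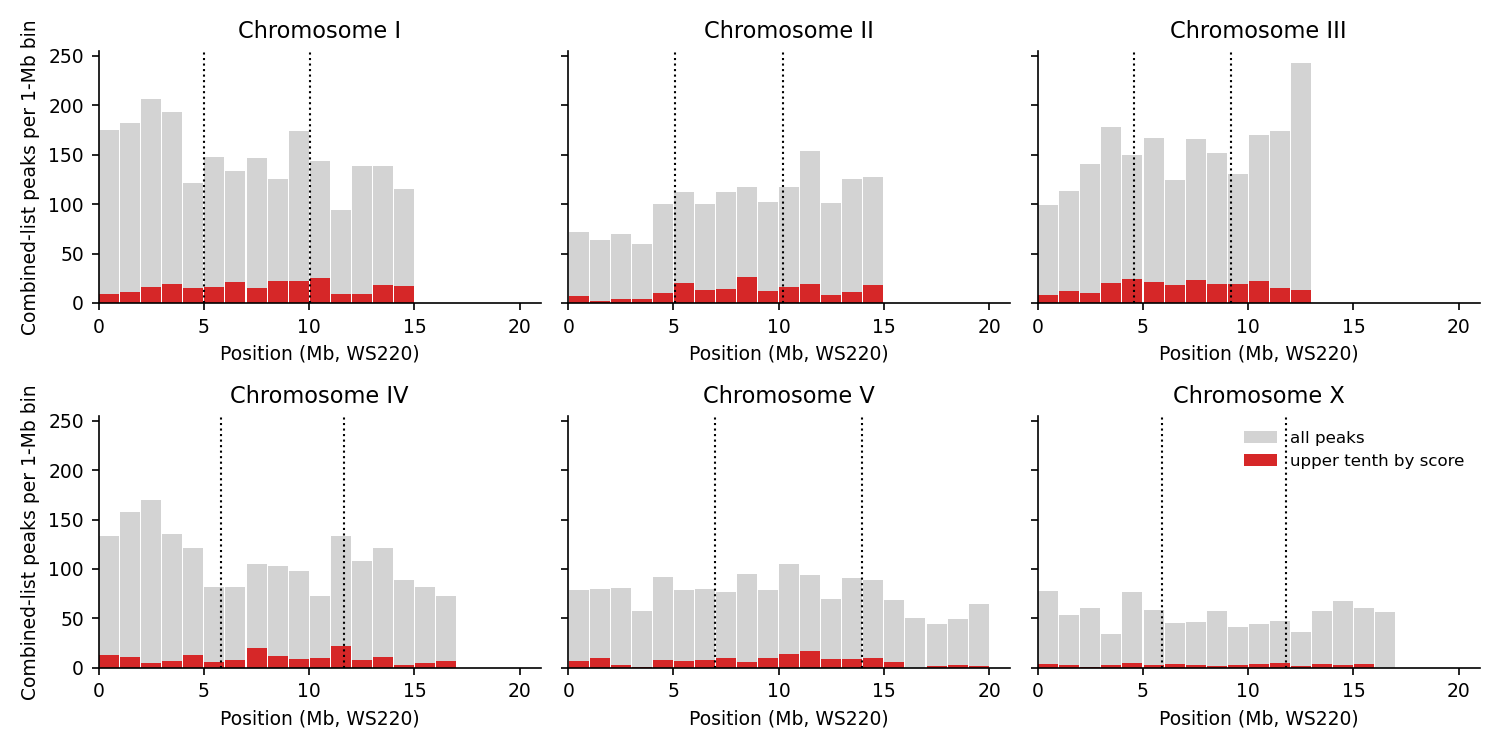
Combined-list peaks per full 1-Mb bin (y axis) along each chromosome (x axis, Mb on WS220); grey bars count all peaks, red bars those in the top 10% by score, and dotted lines mark the 3 equal segments. Bins reach 243 peaks at 12 to 13 Mb of III. Strong peaks were denser in the middle segment, by 1.50-fold on average over the 6 chromosomes (exact sign-flip permutation p = 0.031, adjusted p = 0.344 over 11 settings).

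Some regions carried peaks in replicate 2 and none in replicate 1; these were singled out after their values were seen. Replicate 2 had a peak that began at base 1 of all 6 nuclear chromosomes, with scores of 6.36 on V to 30.51 on I. The first replicate 1 peak on those chromosomes began at base 2153 on I and between base 7679 (V) and base 51279 (IV) on the others. At the right, the last replicate 2 peak of all 6 chromosomes, with scores of 8.43 on II to 15.56 on I, ended 4.38 kb (III) to 25.23 kb (IV) beyond the last replicate 1 peak. The combined list had a peak at 4 of these 12 outermost positions, with scores of 1.9 to 6.83. On chromosome V, 11 consecutive replicate 2 peaks with a median score of 30.7 lay between 17115562 and 17132112. On X, 26 consecutive replicate 2 peaks with a median score of 4.38 lay between 4034055 and 4055897. Mitochondrial DNA carried 1 replicate 2 peak at 13402 to 13667 with a score of 18.15 and 1 combined peak at 13438 to 13638 with a score of 4.77.

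**Figure D4:**
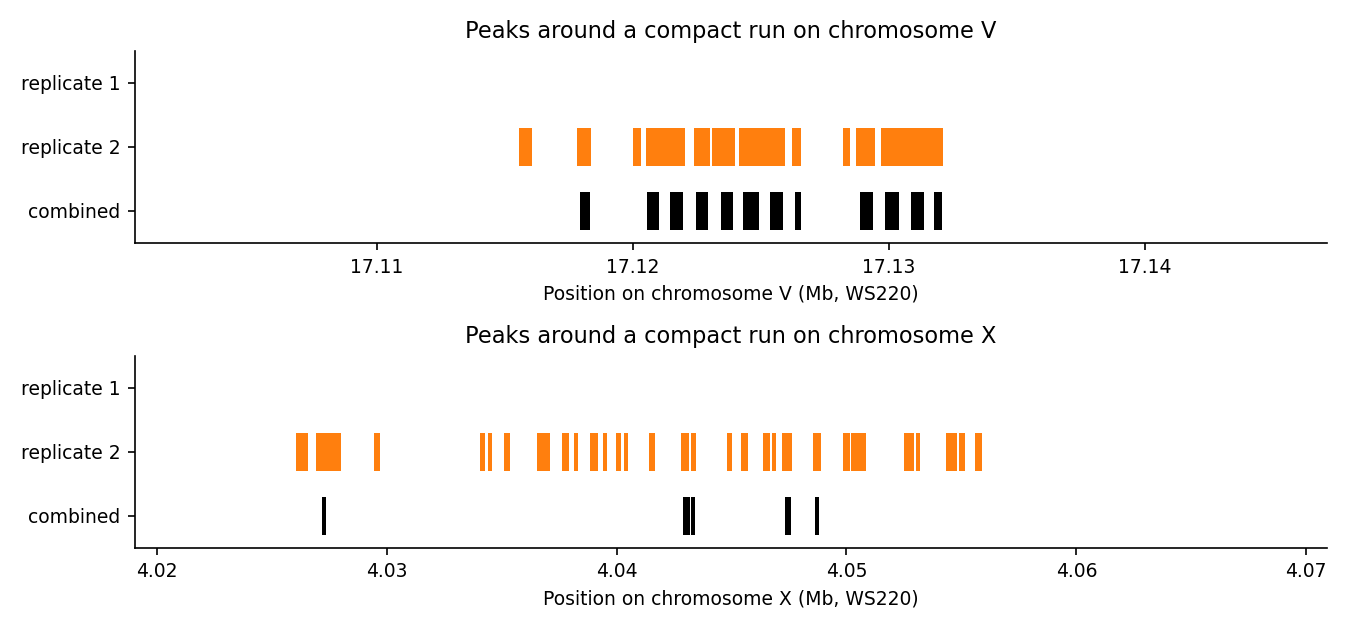
Peaks of the combined list and both replicates, drawn to scale as blocks along chromosome V (top) and X (bottom; x axes, Mb on WS220), around 2 runs of consecutive replicate 2 peaks. Replicate 1 has no peak between the ends of either run, while replicate 2 has runs of 11 peaks on V and 26 on X.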

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

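Over 12 results and 68 alternative values, 49 kept their direction and their side of the threshold or stayed within the interval of the value reported. The overlap between replicates, the score difference between shared and unshared peaks, the rank correlation of scores and the lower density on X did so under every alternative run, though their sizes changed. For X only the direction could change, since the exact permutation p cannot go below 0.167 and so cannot cross the threshold. The share of replicate 1 peaks found in replicate 2 ranged from 48.1% (50% reciprocal overlap) to 73.6% (top 50%) and that of replicate 2 peaks found in replicate 1 from 58.0% to 91.0% under the same settings. The score difference ranged from 23.4 (top 10%) to 74.7 (top 50%) in replicate 1 and from 11.7 (without chromosome ends) to 30.6 (top 50%) in replicate 2. The score cuts were made in both lists and removed partners of lower score, so a positive difference under them is partly built in. The rank correlation ranged from 0.38 (top 10%, where the narrower range of scores by itself lowers it) to 0.89 (50% reciprocal overlap). The X-to-autosome ratio ranged from 0.252 (top 10%) to 0.480 (replicate 2 alone). The shares of the combined list moved with the overlap rule and the score limit. With a 50% reciprocal overlap, 37.9% of combined peaks were in both replicates, 37.9% in replicate 1 alone and 17.7% in neither; with midpoints within 200 bp, 47.5% were in both, 30.4% in replicate 1 alone, 7.24% in replicate 2 alone and 14.9% in neither. With the top 50% of each list the 4 shares were 63.2%, 22.01%, 3.87% and 10.97%, and with the top 10% they were 58.3% in both and 21.5% in replicate 1 alone; by construction these cuts also remove partners of lower score. The mean log2 centre-to-arm ratio was near 0 and not significant in the result reported, and changed sign to 0.12 with the top 50%, 0.59 with the top 10%, 0.13 with peaks in both replicates, 0.13 with covered bases and 0.65 with autosomes alone and the top 10% (exact permutation p = 0.0625, the smallest for 5); the cause was not tested. Each replicate list alone gave ratios of -0.067 and 0.061, and X-to-autosome ratios of 0.423 and 0.480. No paired analysis was possible because the files hold no values for the input libraries that share the replicate numbers. Other settings for peaks near genes and for gene lists were not run, for want of an annotation on WS220. Without reads, the lists cannot show whether an unshared peak is absent from the other replicate or below its threshold.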

Other observations

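The tests of replicate 2 alone, of the chromosome V run, of runs as units and of strong X peaks against random draws, and the use of X ratios and medians to test explanations, were chosen after the result was seen; the X ratios of the combined list's subsets and of each whole replicate list were fixed before the data were examined, and the tests on weak peaks and on the combined list's pooled share of run peaks were set before their results. Regions named here were ranked after the data were seen. The densest 1-Mb bin of the combined list was 12 to 13 Mb of chromosome III with 243 peaks, against a median of 152 over that chromosome's bins. On chromosome I, the bin at 2 to 3 Mb held 206 peaks (median 144), and on IV the bin at 2 to 3 Mb held 170, each of them in the left arm. The sparsest bin of X was at 3 to 4 Mb with 34 peaks and that of V at 17 to 18 Mb with 44. The longest stretch of X free of combined peaks ran from 12021601 to 12293629 (272 kb), with 1 peak in each replicate inside or at its edge. That of V ran from 2891056 to 3088261 (197 kb) and held 3 replicate 2 peaks and no replicate 1 peak. Those of IV, 165 kb from 16224153 to 16389108, and of II, 151 kb from 1509524 to 1660183, held no peak in any list.

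The widest combined peak covered 10000 bp on chromosome II from 10541661 to 10551660, with a score of 107.6, and was split into 5 peaks in replicate 1 and 9 in replicate 2. A 7979 bp peak on II from 14600621 to 14608599 (score 25.8) was split into 6 and 8. A 6638 bp peak on X from 16929364 to 16936001 (score 66.8) was 1 peak in replicate 1 and 2 in replicate 2.

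The peaks at chromosome ends and the compact runs in replicate 2 stand out against an otherwise larger replicate 1 list. The 6 peaks at base 1 were picked because replicate 1 had none there, so their own sharing was not tested. Of 2605 replicate 2 peaks elsewhere in the same score range, 89.2% (Wilson interval 87.9 to 90.3) were shared. Most of the 6 peaks lay low in that range. Among all replicate 2 peaks, 76.7% were shared in the 10% step with scores of 5.57 to 7.42, and 86.2% in that of 7.42 to 10.98. These shares argue against scores too low to be found again. Other sources of the end peaks stay open. Replicate 2 had 22 runs of at least 5 unshared peaks, each within 2 kb of the next. At most 2 such runs arose in 1000 reshufflings of the shared labels within chromosomes. Replicate 1 had 3 runs against at most 10. The reshuffling did not take scores into account, and weak peaks were shared less often. For the replicate 2 runs, chance among neighbouring weak peaks is therefore not excluded. Of the 173 peaks in these runs 27.2% were in the combined list, against 64.1% of the other 1086 unshared replicate 2 peaks, at median scores of 4.80 and 4.44. The runs differed: 9 had no peak in the combined list, 19 had a smaller share there than the other unshared peaks (exact sign test p = 0.00086, two-sided) and 3 a larger one. The runs were picked as groups of unshared peaks and held no replicate 1 peak, while the other unshared peaks could lie close to one. Since the combined list contained 97.8% of replicate 1 peaks, part of the gap may come from how the runs were picked. Signal that the replicate 1 data or its background correction removes is therefore no more than a candidate explanation for part of the runs. For the chromosome V run this stays open. The combined list held 8 of its 11 peaks (72.7%, 43.4 to 90.3) and 75.3% of 292 other unshared replicate 2 peaks in its score range. The run's median score ranked at the 34.8 percentile there, against the 69.2 percentile of replicate 2. That drop cannot decide, since combined peaks found in replicate 2 alone scored low as a group. Their median was 5.69, and the 25th percentile of the combined list was 6.08. Presence in a list does not exclude signal removed in part. In that run, 9 of 11 spacings between neighbouring combined peaks lay within 20% of their median of 986.5 bp, more than in any of 10393 other windows of 12 peaks (highest 8). The run was picked as compact and the other windows were not, so the 2 are not fully alike. A tandemly repeated sequence is no more than a candidate explanation there. In 2 other runs with several combined peaks, 2 of 4 spacings (IV at 15076628) and 1 of 5 (V at 3434627) lay within 200 bp of their median. No sequence was examined under any run, and since the replicates are 1 group no biological explanation was tested.

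The lower density of peaks on X was not owed to weak peaks added elsewhere at the score threshold, since the X-to-autosome ratio was 0.469 among combined peaks found in both replicates and 0.464 in the top 50%. X peaks missed below the threshold are in no list, so that source stays open. Lower read coverage of X, in a population labelled as containing males, could lower scores on X. The peak lists do not give the share of males, so the size of any such effect is unknown. The values were mixed. The ratio in the top 10% was 0.135 in replicate 2 and 0.189 in replicate 1, under the random draws in each. In the top 50% it was 0.492 and 0.446, not below the 0.480 and 0.423 of all peaks. Median scores were higher on X than on autosomes, at 17.8 and 14.76 in replicate 1, 11.5 and 10.9 in replicate 2 and 14.4 and 13.85 in the combined list, though a score threshold also shapes a median. Lower coverage cannot be told apart from fewer strong NURF-1 sites on X, since the lists give no reads, and the gene content and chromatin of X were not tested.

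Weak peaks lay near strong ones somewhat more than chance. Of 2651 combined peaks in the lowest 25% by score, 14.1% (12.9 to 15.5) had a peak of the highest 25% within 1 kb, against a mean of 9.25% and a maximum of 11.3% over 1000 circular shifts. The excess was smaller than shoulders or split peaks as the main source of weak peaks were set beforehand to need (more than 2 times the maximum), and larger than none. Weak peaks near strong ones were found in both replicates in 2.67% of cases and the others in 1.93% (exact Fisher p = 0.327, two-sided), so whether they are sites of their own cannot be told apart from shoulders with so few found in both.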
